A study of Drosophila melanogaster with 4 samples.

How the data were processed

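Total RNA was extracted from adult heads (30 per library) with a phenol-based reagent, libraries were made with the Lexogen SENSE mRNA kit, and a service company carried out quality control and analysis, per the labels' protocols. The authors deposited 1 table of whole-number read counts per gene symbol for each of the 4 libraries, per the file headers a symbol column and a sample column. The genome build was dm6, per the submitters' processing notes; the aligner, the counting tool, the annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here. Each table held 16509 lines, and 37 lines sharing 17 symbols were summed, leaving 16489 symbols. Of these, 16208 (98.3%, holding 98.08% of the counts) were matched by current or older symbol to FlyBase identifiers of the Ensembl release 115 annotation, whose coordinates are those of dm6. Groups came from the sample titles and genotypes, with 2 libraries in each.

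Library totals ran from 15738860 to 18108814 counts, so 3 counts correspond to 0.166 to 0.191 CPM. The 20 most abundant genes took 18.94% to 20.42% of the counts. Between replicates, the variance exceeded that of Poisson counting several-fold even for genes with few counts (mean variance ratio 4.96 in control and 7.18 in yki S168A libraries for pairs totalling 10 to 50 counts).

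Counts were analyzed in edgeR 4.0.16 (R 4.3.3). Genes were kept by filterByExpr with the groups and default minimums, leaving 10896 genes and 5593 untested. Libraries were scaled by TMM, dispersions were estimated with estimateDisp, and yki S168A was compared with control by glmQLFit and glmQLFTest with group as the sole term. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called. The common biological coefficient of variation was 20.7%, and tests used 11.2 degrees of freedom, 2 residual and 9.2 from the prior. Standard errors were taken as the absolute log2 fold change over the square root of F. CPM values are TMM-scaled, and SDs are over the 2 libraries of a group. On simulated counts for the same 10896 genes, the test recovered 52 of 99 genes changed 2-fold and 84 of 100 changed 4-fold, and 8 of its 144 calls were false. The simulation changed only these few genes, drawn from those above a minimum mean count. In the data 27.6% of tested genes were called, so the simulated rates need not hold there.

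Before the data were examined, 40 gene lists, the main test, the alternative settings and the rule for named genes were fixed. The lists covered Yorkie targets and the Hippo pathway, signaling, tumor and immune genes, growth and metabolism, eye, brain, glia, muscle, fat body and blood cell markers, sex-biased genes, and midgut and reproductive genes as markers of tissue other than head. Lists with at least 5 tested members (39) were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over lists; the list of mitochondrially encoded genes matched 0 symbols. Named genes were yki; the 10 higher and 10 lower genes with the largest log2 fold change among called genes with non-overlapping libraries and a mean of at least 10 CPM; of each list up to 4 members, the 3 with the smallest p and the top one called the other way; and a set named in advance (Ilp8, ImpL2, Pvf1, upd3, Mmp1, NUCB1, sNPF, NPF, Lgr3, ex, kibra, th, CycE, fj, dm, ninaE, w, Yp1, roX1). Where 1 group was at 0, the fold was bounded against 3 counts per library.

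The alternatives were RLE and upper-quartile scaling, leaving out the 20 most abundant genes, no filter, a stricter filter at a mean of 10 CPM, legacy and robust quasi-likelihood fits, DESeq2 1.42.0, limma-voom (limma 3.58.1), glmTreat against 1.5-fold, an adjusted p of 0.01, a replicate block, each library left out, and for lists also an estimated correlation, fry and camera on voom values. Chosen after seeing the data were fits with 1 entry kept per set of entries with identical counts, fits with protein-coding genes, the phototransduction median under other scalings, and the spread of its members without Pdh. Overlap of exons with other genes was computed from the annotation for each named gene.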

Results

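RNA was measured in adult heads of Drosophila melanogaster in which the eye driver GMR-Gal4 was present alone (control, n = 2 libraries) or drove an activated form of the transcriptional co-activator Yorkie, yki S168A (n = 2 libraries). The serine replaced in this form is a site through which the Hippo pathway kinase Warts restrains Yorkie, and the series describes the transgenic heads as tumor tissue. Each library was made from 30 heads. The count tables summed to 16817968 and 15738860 reads for the control libraries and to 17311383 and 18108814 for the yki S168A libraries. Nothing in the labels says that the libraries came from separate cultures or crosses, so p-values measure only the spread between these samples, which may be technical. Across genes, log2 CPM (counts scaled to the library total) correlated at r = 0.975 between the control libraries, at 0.964 between the yki S168A libraries and at 0.903 to 0.917 across the groups, where genes are not independent replicates.

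The single comparison of the design sets heads with activated Yorkie in the eye against heads with the driver alone. Effects of Yorkie activity, of the transgene insertion itself and of any difference in stock background cannot be told apart in it. In heads with yki S168A, 30 of 42 phototransduction genes were lower and 3 higher, with a median log2 fold change of −1.25 and the opsin Rh6 215-fold lower (adjusted p = 0.524 for the list with an estimated correlation). Of 42 immune effector genes 28 were higher and 1 lower, with IM1 at 25.6-fold, and of 31 secreted factors reported from fly tumors 16 were higher and 5 lower, with the insulin-binding protein gene ImpL2 at 6.59-fold (adjusted p = 0.531 for each list with an estimated correlation). More members were higher than lower among proteasome subunits (29 and 0 of 32). The joint list of JNK targets and apoptosis genes (11 and 0 of 26) went the same way. So did the joint list of glutathione S-transferases and cytochrome P450s (34 and 15 of 102). More were lower than higher among fat body (17 and 2 of 28), neuronal (24 and 2 of 38), feeding peptide (16 and 2 of 39) and stress genes (17 and 10 of 41). These lists passed with a preset inter-gene correlation, and 0 of the 39 lists tested passed with an estimated one (lowest adjusted p = 0.524). The latter setting uses the 2 residual degrees of freedom, which makes a pass hard at any correlation. Of 10896 genes tested, 3006 (27.6%) changed at an adjusted p below 0.05 by edgeR's quasi-likelihood test, 1647 higher and 1359 lower. Among them, 887 were higher and 628 lower by more than 2-fold.

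The direction split of these calls depended on the scaling of the libraries. With upper-quartile factors, 1276 genes were higher and 1924 lower, and the median log2 fold change over all tested genes moved from 0.01 to −0.15. The number of genes changed was 1634 without control replicate 1 (983 higher, 651 lower) and 1696 without control replicate 2 (1048 higher, 648 lower).

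The yki gene itself (FBgn0034970, chromosome 2R, 24065975 to 24068485, minus strand, build dm6) was at 12.4 and 18.4 CPM in the control libraries and at 32.2 and 27.2 CPM in the yki S168A libraries. Its mean was 15.4 ± 4.26 CPM in control and 29.7 ± 3.57 CPM in transgenic heads (SD, n = 2 each), a log2 fold change of 0.95 ± 0.23 (SE, edgeR adjusted p = 0.0112). Reads of the transgene and of the resident gene cannot be separated in gene counts, and the difference did not pass without control replicate 1 (log2 fold change 0.69, adjusted p = 0.138). The eye color gene w, which is also the usual marker carried by fly transgenes, was at 6.12 ± 0.02 CPM in control and 55.1 ± 6.9 CPM in yki S168A heads, 8.98-fold higher (adjusted p = 1.33e-06).

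**Figure D1:**
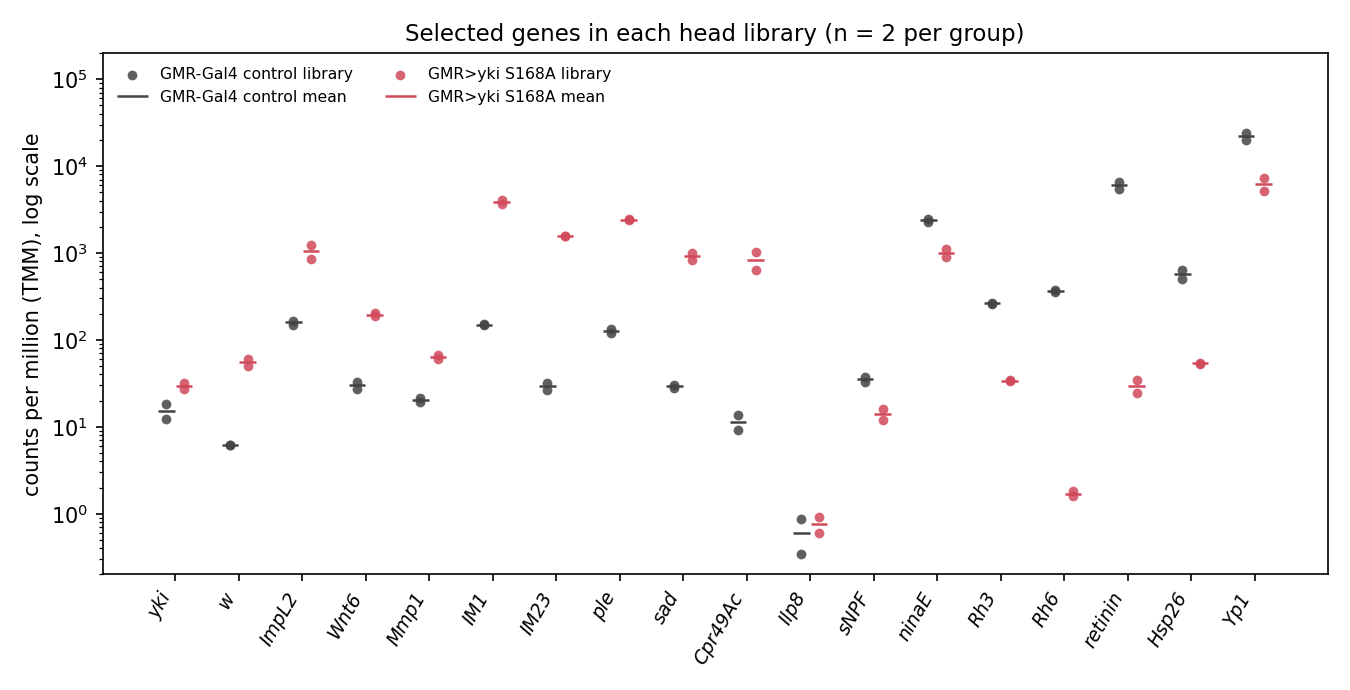
CPM (TMM-scaled, log axis) of 18 genes in each of the 4 head libraries; points are libraries and short lines are group means (n = 2 per group), gray for GMR-Gal4 control and red for GMR>yki S168A. The libraries of the groups do not overlap for any plotted gene except Ilp8, which lies below 1 CPM in all 4.

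The 10 largest increases among well-expressed genes were led by CG5909 (FBgn0039495, chromosome 3R, 27161158 to 27162911), at 0.494 ± 0.351 CPM in control and 370 ± 31.6 CPM in yki S168A heads (SD, n = 2 each). Its log2 fold change was 9.50 ± 0.28 (SE, adjusted p = 4.8e-09), and it became 10.51 without control replicate 1. CG45060 had 2 and 3 counts in the control libraries and 1332 and 1711 in the yki S168A libraries, so its log2 fold change of 9.16 (95% interval 8.45 to 9.88) rests on few control counts. CG42792 rose from 0.246 to 49.9 CPM. The CG42792 fold change also rested on few control counts, 0 in replicate 1 and 8 in replicate 2, and its log2 value moved from 7.68 to 6.65 without control replicate 1 and to 6.68 without yki S168A replicate 2. Without control replicate 2 the remaining control library is at 0, so no fold is given. Cuticle protein genes Pcp (98.3-fold) and Cpr49Ac (73.6-fold), the immune peptide gene IM23 (54.2-fold) and the uncharacterized genes CG15674, CG16772 and CG14567 (66.0-, 58.5- and 39.7-fold) and CG14752 (log2 fold change 5.25) completed the 10. Pcp was 59.2-fold higher without yki S168A replicate 1. An antisense gene overlaps 78.1% of the exonic bases of CG15674, so its reads cannot be assigned to 1 strand here.

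Rh6 (FBgn0019940, chromosome 3R, 15483158 to 15484699) showed the largest fall of the corresponding 10 decreases, from 367 ± 11.5 to 1.70 ± 0.17 CPM (log2 fold change −7.75 ± 0.21, adjusted p = 4.8e-09). The corneal lens gene retinin (FBgn0040074, chromosome 3L, 16331933 to 16332789) fell from 6035 ± 783 to 29.4 ± 6.89 CPM. The sugar-responsive glucosidase gene tobi fell 35.5-fold, and 70.8-fold without yki S168A replicate 2. CG13670 fell by 4.98 on the log2 scale, and 52.1-fold without yki S168A replicate 2. Pdh, a pigment-cell retinol dehydrogenase of the visual cycle, fell by 4.18 on the log2 scale, and the neighboring CG4933 fell by 3.79 on the log2 scale. Of the exonic bases of Pdh 43.3% lie opposite other genes, CG4933 (now Tcs3) among them, and of those of CG4933 4.6% lie opposite Pdh. CR31084 and CG34291, which overlap on opposite strands, fell by 3.87 and 3.25 on the log2 scale. CG4842 fell by 3.65 on the log2 scale and the small heat shock gene Hsp26 10.5-fold. The genes retinin, CG4933, Pdh and CG4842 all lie between positions 16331933 and 16369518 of chromosome 3L. Their falls may therefore not be independent, and a shared local cause was not tested.

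Of 39 gene lists tested with camera, 13 passed at an adjusted p below 0.05, 6 upward and 7 downward. With an estimated inter-gene correlation in place of the preset 0.01, 0 of the 39 lists passed at an adjusted p below 0.05. Camera then uses the 2 residual degrees of freedom, so a list could hardly pass at any correlation. Each of the 13 lists is given below with its adjusted p under both settings. With fry, which asks whether the genes of a list move on balance one way and compares them with no other genes, 16 lists passed. They took in 8 lists that camera did not call: Yorkie targets (adjusted p = 0.0342), Hippo components (0.0244), Notch, Wingless, EGFR and Hedgehog genes (0.039), cell cycle (0.0486), DNA replication (0.039), extracellular matrix (0.0417), glia (0.039) and midgut (0.0486). They left out 5 that it did: immune effectors (adjusted p = 0.0544), proteasome (0.0538), stress (0.0616), neuronal (0.0749) and respiratory chain genes (0.114). Below, a list that passed or did not pass did so by camera unless another test is named.

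Phototransduction genes fell as a list (30 of 42 tested members lower, 3 higher, both over all genes and adjusted over the list alone, median log2 fold change −1.25, adjusted p = 1.49e-22, and adjusted p = 0.524 with an estimated correlation). The opsin Rh3 fell from 263 ± 8.05 to 33.8 ± 0.83 CPM (SD, n = 2 each). The main opsin of the outer photoreceptors, ninaE, fell less, from 2371 ± 128 to 1002 ± 151 CPM (2.37-fold, adjusted p = 0.000536). Inos, the inositol phosphate synthase gene, went the other way, 4.33-fold higher. Lens and cone cell genes did not pass as a list (5 of 12 lower, 4 higher, 6 and 4 adjusted over the list alone, adjusted p = 0.0981). In it retinin fell, while CG10663 rose 8.12-fold and the chitin-binding Gasp 4.05-fold. Eye pigment genes went both ways (9 of 21 higher and 5 lower, the same numbers adjusted over the list alone, adjusted p = 0.148), with w and the pteridine synthesis gene Pu (3.05-fold) higher and pr 1.95-fold lower. Eye determination factors did not pass (3 of 24 higher and 5 lower, 4 and 6 adjusted over the list alone, adjusted p = 0.268); oc fell 2.25-fold and toe rose 2.14-fold.

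Immune effector genes rose as a list (28 of 42 higher and 1 lower, 29 and 2 adjusted over the list alone, median 1.52, adjusted p = 7.88e-24, and adjusted p = 0.531 with an estimated correlation). IM23, a Bomanin now called BomBc1, rose from 29.2 ± 3.74 to 1586 ± 2.48 CPM (SD, n = 2 each). The Bomanin gene IM1 rose from 150 ± 0.91 to 3844 ± 282 CPM and CG33470, now BaraA1, 11.1-fold. The antimicrobial peptide gene Def was 1.75-fold lower (adjusted p = 0.0423), a call lost without control replicate 2 (adjusted p = 0.412) or yki S168A replicate 2 (adjusted p = 0.172). Hemocyte markers did not pass as a list (5 of 23 higher and 5 lower, 7 and 5 adjusted over the list alone, adjusted p = 0.819); NimC4 rose 2.01-fold and peb fell 2.22-fold.

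Secreted factors reported from fly tumors rose as a list (16 of 31 higher and 5 lower, 18 and 5 adjusted over the list alone, median 0.94, adjusted p = 0.000468, and adjusted p = 0.531 with an estimated correlation). The list did not pass with the filter at a mean of 10 CPM (adjusted p = 0.0577). ImpL2, 61.9% of whose exonic bases are shared with CG46460 on the same strand, rose from 159 ± 11.8 to 1046 ± 271 CPM, the ligand gene Wnt6 6.49-fold and the metalloprotease inhibitor gene Timp 3.63-fold. The matrix metalloprotease gene Mmp1 rose 3.09-fold (adjusted p = 3.86e-05) and the growth factor gene Pvf1 3.10-fold (adjusted p = 0.00754), the latter not without control replicate 2 (adjusted p = 0.052). The cytokine gene upd3 had 0 counts in both control libraries and 99 and 28 counts in the yki S168A libraries, at least 21.4-fold higher against a floor of 3 counts per library (adjusted p = 0.00688). For upd3 the bound was at least 8.94-fold without yki S168A replicate 1 (adjusted p = 0.0254) and at least 33.8-fold without yki S168A replicate 2 (adjusted p = 0.000811). The activin-like ligand gene daw fell 2.23-fold. Ilp8, the relaxin-like peptide gene secreted by growing fly tumors, had 6 and 14 counts in control and 10 and 16 counts in yki S168A libraries; no difference was detectable at this depth (log2 fold change 0.36, 95% interval −1.49 to 2.21, adjusted p = 0.801). Its receptor gene Lgr3 had 8 and 21 counts in control and 12 and 4 in yki S168A libraries (adjusted p = 0.540). The labels name no molecular identifiers, so floors cover counting error only, and intervals add to it no more than the fitted spread between these libraries.

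The joint list of JNK targets and apoptosis genes rose (median 0.44, adjusted p = 0.00146, and adjusted p = 0.531 with an estimated correlation). In it 11 of 26 members were higher and 0 lower, 12 and 0 adjusted over the list alone. The transcription factor gene Ets21C rose 3.96-fold, scaf 5.40-fold and the filamin gene cher 4.08-fold. Outside the rule for named genes, puc was not called (log2 fold change 0.13, edgeR adjusted p = 0.611). The apoptosis genes rpr (0.33, adjusted p = 0.705), grim (−0.09, 0.949) and skl (−1.18, 0.3) were not called either, while Ice was higher (0.93, 0.0332). JAK/STAT genes rose (9 of 19 higher and 2 lower, 10 and 4 adjusted over the list alone, median 0.75, adjusted p = 0.0166, and adjusted p = 0.531 with an estimated correlation). The list did not pass with the filter at a mean of 10 CPM (adjusted p = 0.235). In it the stress-induced TotM rose 4.25-fold, et 3.24-fold and the receptor gene dome 2.54-fold, whereas TotA fell 2.06-fold. The upd3 gene belongs to both of these lists, to the secreted factors and to the Yorkie targets. Mmp1, egr and Pvf1 are shared by the JNK list and the secreted factors. The genes os and upd2 are shared by the JAK/STAT list, the secreted factors and the Yorkie targets. The rises of these lists are therefore not independent.

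Proteasome subunits rose almost uniformly (29 of 32 higher and 0 lower, 32 and 0 adjusted over the list alone, median 0.79, adjusted p = 3.21e-08, and adjusted p = 0.531 with an estimated correlation). Prosalpha4 rose 2.42-fold, Prosalpha6 2.05-fold and Rpn2 1.80-fold. Glutathione S-transferases and cytochrome P450s rose on balance (34 of 102 higher and 15 lower, 38 and 19 adjusted over the list alone, median 0.24, adjusted p = 0.00738, and adjusted p = 0.531 with an estimated correlation). GstD9 rose 10.6-fold, GstD3 7.46-fold and GstE14 4.26-fold, and the ecdysone-inactivating Cyp18a1 fell 3.04-fold.

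The stress list, which joins heat shock and detoxification genes, fell on balance (17 of 41 lower and 10 higher, 20 and 13 adjusted over the list alone, median −0.45, adjusted p = 0.00244, and adjusted p = 0.531 with an estimated correlation). Among its members, Hsp26 fell from 568 ± 100.4 to 54.1 ± 1.11 CPM, Hsp68 7.27-fold and Hsp27 8.36-fold, while GstE6 rose 7.54-fold. Hsp70Aa and Hsp70Ab carried identical counts in all 4 libraries, so they are not separate measurements.

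Yorkie target genes did not pass as a list (10 of 22 higher and 2 lower, 11 and 2 adjusted over the list alone, median 0.59, adjusted p = 0.0896). Among established targets, kibra rose from 57.8 ± 4.46 to 114 ± 5.2 CPM (adjusted p = 0.000585) and jub 2.19-fold. The caspase inhibitor gene th, also called Diap1, rose 1.69-fold (adjusted p = 0.00328), a call lost without control replicate 1 (adjusted p = 0.0764). The target gene ex was at 20.5 ± 1.76 and 30.2 ± 1.88 CPM and missed the threshold (adjusted p = 0.0509). For gene ex, adjusted p ran from 0.0307 with a replicate block to 0.149 with upper-quartile scaling among fits to all 4 libraries. CycE (adjusted p = 0.186) and fj (adjusted p = 0.552) did not pass. The Myc gene, listed as dm, fell from 508 ± 13.3 to 293 ± 10.6 CPM (adjusted p = 0.00159), with 40.9% of its exonic bases opposite other genes and 20.3% shared with other genes on the same strand. Hippo pathway components did not pass as a list (10 of 30 higher and 0 lower, 11 and 0 adjusted over the list alone, adjusted p = 0.12), with lft 4.10-fold and the atypical cadherin gene ds 3.97-fold higher. Notch, Wingless, EGFR and Hedgehog genes did not pass (12 of 35 higher and 4 lower, the same numbers adjusted over the list alone, adjusted p = 0.0896); the Hedgehog receptor gene ptc rose 7.76-fold, E(spl)mbeta-HLH 4.84-fold and dpp 2.46-fold, and kek1 fell 1.62-fold, a call lost without control replicate 2 (adjusted p = 0.166).

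Proliferation genes did not pass as lists. Of 44 cell cycle genes 6 were higher and 2 lower (5 and 1 adjusted over the list alone, adjusted p = 0.312), and of 40 DNA replication genes 4 were higher and 2 lower (3 and 1 adjusted over the list alone, adjusted p = 0.401). The sliding clamp gene PCNA rose 4.38-fold, the anillin gene scra 4.98-fold and RnrS 2.79-fold, while the origin-licensing gene Cdc6 fell 6.70-fold. Ribosome biogenesis genes (1 of 43 higher and 2 lower, 1 and 1 adjusted over the list alone, adjusted p = 0.462), cytosolic ribosomal proteins (1 of 83 higher and 0 lower, 0 and 0 adjusted over the list alone, adjusted p = 0.825), mitochondrial ribosomal proteins (0 of 72 higher and 3 lower, 0 and 0 adjusted over the list alone, adjusted p = 0.312) and replication-dependent histones (0 of 56 either way, also adjusted over the list alone, adjusted p = 0.285) showed few or no calls.

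Neuronal and synaptic genes fell as a list (24 of 38 lower and 2 higher, 27 and 2 adjusted over the list alone, median −0.62, adjusted p = 0.000386, and adjusted p = 0.531 with an estimated correlation). Syt4 fell 1.99-fold and the choline acetyltransferase gene, listed as Cha, 1.73-fold. The tyrosine hydroxylase gene ple, which makes the precursor of dopamine and of cuticle cross-linking compounds, rose from 126 ± 8.51 to 2414 ± 61.7 CPM (19.1-fold). Glial markers did not pass as a list (7 of 23 higher and 2 lower, the same numbers adjusted over the list alone, adjusted p = 0.178); moody rose 4.99-fold, cv-c 2.39-fold and Nrx-IV 2.62-fold, and Tret1-1 fell 1.94-fold. Clock genes and outputs fell (8 of 18 lower and 1 higher, 9 and 2 adjusted over the list alone, median −0.52, adjusted p = 0.0276, and adjusted p = 0.531 with an estimated correlation). The list did not pass with the filter at a mean of 10 CPM (adjusted p = 0.0591). The clock neuropeptide gene Pdf fell 2.30-fold, its receptor gene Pdfr by 0.71 on the log2 scale and sgg 1.66-fold. The Pdfr call was lost without control replicate 1 (adjusted p = 0.052).

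Feeding-related peptides and receptors fell as a list (16 of 39 lower and 2 higher, 17 and 2 adjusted over the list alone, median −0.79, adjusted p = 0.00584, and adjusted p = 0.531 with an estimated correlation). The neuronal list above had a median of −0.62, and whether the feeding list fell beyond it was not tested. The appetite-promoting peptide gene sNPF fell from 35.3 ± 3.01 to 14.2 ± 2.93 CPM (2.49-fold, adjusted p = 0.000944) and CCHa2 fell 2.06-fold. NPF fell 1.73-fold (adjusted p = 0.0369), and did not pass without control replicate 1 (adjusted p = 0.155), control replicate 2 (adjusted p = 0.156) or yki S168A replicate 1 (adjusted p = 0.111). The nesfatin-related NUCB1 rose 1.52-fold (adjusted p = 0.011), and did not pass without control replicate 1 (adjusted p = 0.122) or 2 (adjusted p = 0.0896). The adipokinetic hormone gene Akh rose from 0.303 ± 0.266 to 8.78 ± 3.23 CPM, 29.1-fold; the fold was 17.7 without control replicate 1 and 72.5 without control replicate 2. Antennal and other chemosensory genes did not pass as a list (10 of 27 lower and 4 higher, 12 and 4 adjusted over the list alone, adjusted p = 0.0715), nor did odorant receptors (1 of 9 higher and 0 lower, the same numbers adjusted over the list alone, adjusted p = 0.825). Obp83a fell 3.60-fold and a10 3.42-fold, and Obp57a rose 1.96-fold. The antennal list passed without control replicate 1 (adjusted p = 0.0249).

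Fat body and hemolymph protein genes fell (17 of 28 lower and 2 higher, 18 and 2 adjusted over the list alone, median −0.80, adjusted p = 1.12e-06, and adjusted p = 0.524 with an estimated correlation). Pepck, the gluconeogenic enzyme gene, fell from 1578 ± 61.4 to 380 ± 79.1 CPM, and Obp99a fell 9.14-fold (17.1-fold without yki S168A replicate 1). The yolk protein gene Yp1, expressed in female fat body, fell 3.53-fold (adjusted p = 0.00148), a call lost without control replicate 2 (adjusted p = 0.0681). An antisense gene overlaps 54.3% of the exonic bases of Yp1. Female-biased head genes did not pass as a list (4 of 6 lower and 1 higher, 5 and 1 adjusted over the list alone, adjusted p = 0.0981) and male-biased ones did not either (1 of 8 higher and 2 lower, the same numbers adjusted over the list alone, adjusted p = 0.598). The male-specific dosage compensation RNA roX1 was at 2205 ± 129 and 1985 ± 467 CPM (adjusted p = 0.637), and was lower without yki S168A replicate 1 (log2 fold change −0.42, adjusted p = 0.0365). The female-biased list passed with a replicate block (adjusted p = 0.0169), with camera on voom values (adjusted p = 0.0334), and without control replicate 1 (adjusted p = 0.0159), control replicate 2 (adjusted p = 0.0439) or yki S168A replicate 1 (adjusted p = 5.85e-05).

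Nuclear genes of the respiratory chain fell slightly (16 of 73 lower and 0 higher, 1 and 0 adjusted over the list alone, median −0.35, adjusted p = 0.00104, and adjusted p = 0.689 with an estimated correlation), with SdhA 1.57-fold lower. The SdhA call was lost without control replicate 1 (adjusted p = 0.0691). Glycolysis genes went both ways (7 of 21 higher and 5 lower, 7 and 6 adjusted over the list alone, adjusted p = 0.766), with Hex-A 2.65-fold higher and Hex-C 2.36-fold lower. Insulin pathway genes did not pass (4 of 23 higher and 5 lower, the same numbers adjusted over the list alone, adjusted p = 0.28); ImpL2 rose and tobi and sug fell, sug by 3.61-fold. Ecdysone and juvenile hormone genes did not pass (1 of 31 higher and 7 lower, the same numbers adjusted over the list alone, adjusted p = 0.28), and the ecdysteroid synthesis gene sad rose from 29.1 ± 1.57 to 918 ± 116 CPM while Hr38 fell 4.70-fold.

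Extracellular matrix genes did not pass (7 of 23 higher and 4 lower, the same numbers adjusted over the list alone, adjusted p = 0.12), with the matrix protein gene Tig 13.7-fold higher and Glt at a log2 fold change of −0.67, a call lost without control replicate 2 (adjusted p = 0.0806). The list passed without yki S168A replicate 1 (adjusted p = 0.0444). Cuticle proteins did not pass (19 of 56 higher and 10 lower, 20 and 12 adjusted over the list alone, adjusted p = 0.0896); besides Cpr49Ac and Pcp, Cpr76Bc rose 5.28-fold and Ccp84Ag fell 6.01-fold. The cuticle list passed with the filter at a mean of 10 CPM (adjusted p = 0.0095), with a replicate block (adjusted p = 0.0133), without control replicate 1 (adjusted p = 0.0115) and without yki S168A replicate 1 (adjusted p = 0.000539). Muscle genes showed 1 of 29 higher and 1 lower (0 and 1 adjusted over the list alone, adjusted p = 0.462) and passed as a list without yki S168A replicate 2 (adjusted p = 0.0304). Of the lists for tissue other than head, midgut enzymes had 1 of 5 higher and 0 lower (the same numbers adjusted over the list alone, adjusted p = 0.28), Mal-A2 being at 0 in both control libraries and at least 76.0-fold higher. Reproductive genes had 3 of 8 higher and 1 lower (3 and 2 adjusted over the list alone, adjusted p = 0.766), with the eggshell gene Cp16 at 0 in both control libraries and at least 11.5-fold higher and Cp19, at 0 and 4 counts in the yki S168A libraries, 46.1-fold lower. The Cp16 call was lost without control replicate 1 (adjusted p = 0.0632), control replicate 2 (adjusted p = 0.0555) or yki S168A replicate 2 (adjusted p = 0.058). The Cp16 bound was at least 17.2-fold without yki S168A replicate 1 and at least 5.81-fold without yki S168A replicate 2, and the Cp19 fold was 24.6 without yki S168A replicate 1. Without yki S168A replicate 2 the remaining library of that group is at 0 for Cp19, so no fold is given. Median, mean and test direction differed in sign for glycolysis, reproductive, hemocyte, cytosolic ribosome and odorant receptor genes, none of which passed.

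**Figure D2:**
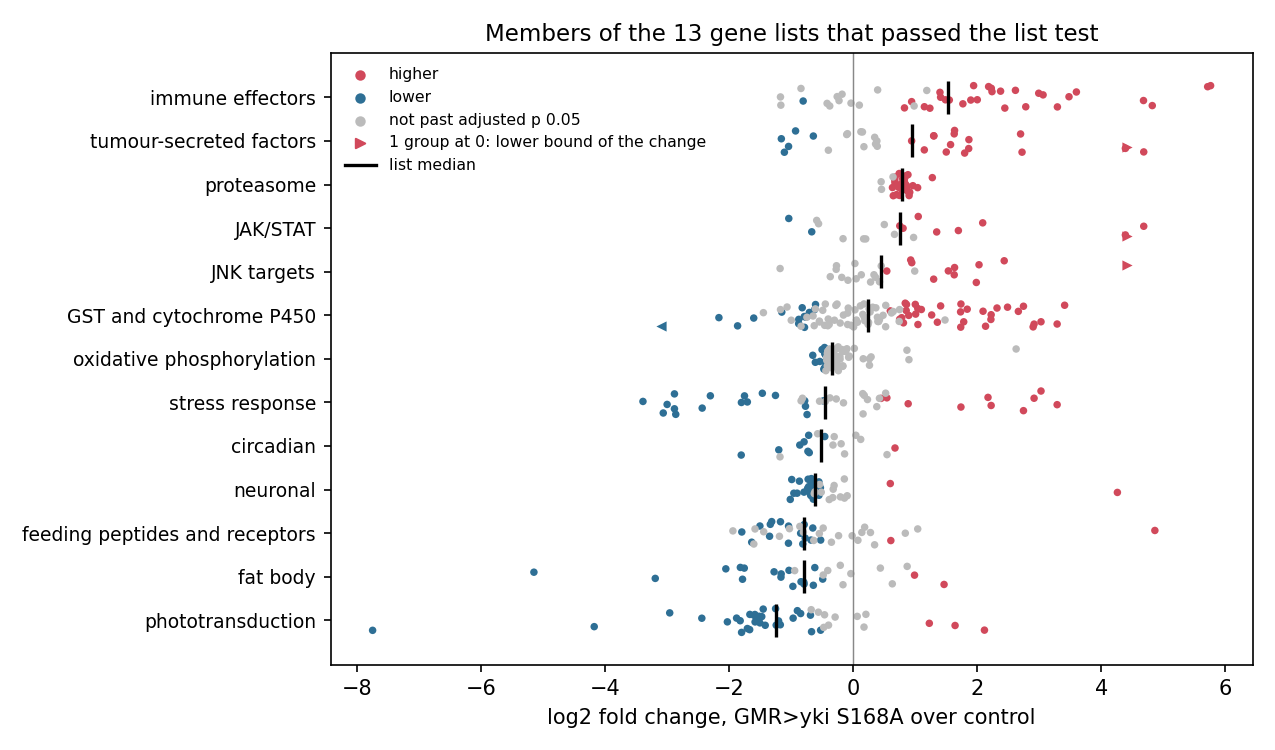
Log2 fold change (GMR>yki S168A over control, horizontal axis) of each tested member of the 13 gene lists that passed camera; red points were higher, blue points lower and gray points did not pass an adjusted p of 0.05 by edgeR, triangles mark lower bounds where 1 group had 0 counts, and black lines are list medians. Medians run from −1.25 for phototransduction to 1.52 for immune effectors.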

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

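Tests with 1 entry kept per set of entries with identical counts, with protein-coding genes, of the phototransduction median under other scalings and of its spread without Pdh were chosen after seeing the data. Of 149 named genes, 133 were called. The alternatives checked for named genes changed the scaling, filter or model, added a block, or left out libraries or the most abundant genes. Under every such alternative that tested them, 107 of the called genes kept their direction and call. Another 26 lost the call in at least 1, and 0 of the called genes reversed. Calls of named genes were not checked under glmTreat, the stricter adjusted p, or the fits chosen after seeing the data. The genes that reversed were not called. Without single libraries the log2 fold change ran from −0.18 (without control replicate 1) to 1.13 for gene Ilp8, from −1.89 to 0.038 (without control replicate 2) for gene Lgr3, from −0.092 (without yki S168A replicate 2) to 0.73 for gene fj and from −0.42 to 0.067 (without yki S168A replicate 2) for gene roX1. For yki expression it ran from 0.69 to 1.26, and the call was lost without control replicate 1. These fits have fewer samples, and the lone library of a group was assumed to vary like the other group.

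Against 3006 genes changed (1647 higher, 1359 lower, 887 and 628 over 2-fold), glmTreat gave 1180 (750 and 430, with 410 lower over 2-fold) and an adjusted p of 0.01 gave 1691 (1074 and 617, with 364 lower over 2-fold), both stricter by construction. The filter at 10 CPM, which tested 6681 genes, gave 333 lower over 2-fold. Leaving out single libraries gave 1634 to 3123 genes changed, 983 to 1688 higher and 648 to 1435 lower, with 413 to 676 lower over 2-fold. DESeq2 shared 2744 calls in the same direction with the edgeR test and limma-voom 2880. Protein-coding genes alone gave 1553 higher and 1260 lower.

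Of the 13 lists called, 0 passed with an estimated correlation (lowest unadjusted p 0.0227). That setting uses the 2 residual degrees of freedom, so passing was hard at any correlation. Fat body (estimate −0.008, camera p 1.14e-07 to 0.0269) and JNK targets (−0.034, 0.000298 to 0.0561) lost their calls with estimates below 0.01. Feeding peptide (−0.014), JAK/STAT (−0.001) and clock genes (−0.05) did too. For these lists higher correlation is argued against as the reason. The other called lists had estimates above the preset 0.01. These were 0.553 for proteasome, 0.478 for immune effector, 0.43 for respiratory chain, 0.213 for neuronal and 0.111 for stress genes. The secreted factors had 0.1, phototransduction 0.058 and the joint list of glutathione S-transferases and cytochrome P450s 0.041. Their p-values at the preset 0.01 therefore rest on a lower correlation than was estimated. Whether the correlation or the degrees of freedom cost them the call was not tested. The 39 lists kept their side of the threshold under RLE and upper-quartile scaling, and the 13 called lists also kept their direction. With the filter at 10 CPM the secreted factors, JAK/STAT and clock lists did not pass and the cuticle list did. With fry 5 called lists did not pass and 8 uncalled ones did, Yorkie targets and cell cycle genes among them. The female-biased list passed with camera on voom values. The replicate numbers 1 and 2 recur in both groups, and deviations of same-numbered libraries correlated at 0.018. A replicate block gave 3626 genes changed (1903 higher, 1723 lower), 15 lists (the female-biased and cuticle lists added) and a log2 fold change of 0.96 for yki expression. Ilp8 and Lgr3 had 4 to 21 counts per library, so both depth and the spread between libraries bear on them. Pseudocount alternatives applied to normalized values alone and were not run.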

Other observations

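Tests of phototransduction, fat body and yolk protein genes, of the Hsp70 copies, of handling, of septate junction genes and of 5S rRNA copies were chosen only after the result was seen. The test of further heat shock genes had its prediction written before their values were examined. A first run of the septate junction list left out 1 member by mistake, and the list was restored to its first wording after that run had been seen. Genes named in this part outside the rule for named genes were chosen after their values were seen. Of 16 tested tetraspanin genes of the Tsp42E cluster on chromosome 2R, 9 were higher and 2 lower by edgeR, and no enrichment was tested. Tsp42Ed rose from 75.7 ± 13.6 to 522 ± 68.8 CPM, Tsp42El 6.63-fold and Tsp42Ei 6.32-fold, whereas Tsp42Ej was at 131 ± 2.72 CPM in control and 69.8 ± 2.21 CPM in yki S168A heads (SD, n = 2 each). The metallothionein gene MtnA rose from 1126 ± 28.1 to 5074 ± 335 CPM, and the RNA helicase gene mle from 142 ± 3.29 to 1419 ± 50.8 CPM. The astrocyte marker alrm was at 20.9 ± 0.69 and 19.6 ± 0.9 CPM and the glial repo at 15.4 ± 0.93 and 16.3 ± 1.36 CPM (adjusted p = 0.785 and 0.850).

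Several junction genes were higher among the glial markers (moody, Nrx-IV), which raised the hypothesis that components of the septate junction, the barrier junction of epithelia and glia, rose as a set. Of 16 further components, of which dlg1 (log2 fold change −0.21, adjusted p = 0.308) had also been tested in the neuronal list, 14 were higher and 1 lower, with a median log2 fold change of 1.28 and a camera p of 1.31e-08 (p = 0.0258 with an estimated correlation). Both p-values are unadjusted. Among the lists fixed in advance, a camera p of 0.0227 with an estimated correlation did not pass after adjustment (adjusted p = 0.524). Lac rose from 27.0 ± 0.75 to 111 ± 3.51 CPM and cold from 13.6 ± 1.49 to 55.0 ± 8.39 CPM, while CG13704, now hoka, fell by 3.05 on the log2 scale. The cell type, epithelium or glia, was not tested.

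Phototransduction genes were lower. A smaller share of photoreceptor RNA could dilute all photoreceptor genes alike. Of the 30 members called lower, 36.7% had a 95% interval that left out their median of −1.53. Rh6, Rh3, Rh4, trpl and Pdh lay below it and inaC, inaD, inaE, rdgB, CdsA and Tsp42Ek above it. Without Pdh, a pigment-cell gene, 34.5% of 29 members had such an interval. Any member also expressed outside photoreceptors would fall less under such dilution, so those above the median cannot decide. The opsins called lower had log2 fold changes of −7.75 (Rh6), −2.96 (Rh3), −2.44 (Rh4), −1.24 (ninaE) and −1.18 (Rh2). These values argue against equal dilution of the opsin genes. The choice among the scalings tried is argued against as well, since the list median was at most −1.25 under 3 other scalings. The median over all tested genes was −0.01 with RLE, −0.145 with upper-quartile factors and 0.013 without the 20 most abundant genes. A larger error of scaling was therefore not tested. Loss of particular photoreceptor types together with lower expression may remain as an explanation and was not tested. Rh5, like Rh6 an opsin of inner photoreceptors, had a log2 fold change of 0.17 (95% interval −0.15 to 0.50, edgeR adjusted p = 0.432).

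Fat body genes, yolk proteins included, were lower. Fewer female heads in the transgenic libraries could lower sex-biased genes, but 12 of the 22 members without sex-biased genes were lower too, which argues against sex makeup as the cause of that part. For Yp1, Yp2 and Yp3 the sex makeup cannot be told apart from the transgene: roX1 had a log2 fold change of −0.15 and roX2 of 0.23, neither called with all 4 libraries, and the labels used here give no sex. Without yki S168A replicate 1 roX1 was called lower (log2 fold change −0.42, adjusted p = 0.0365), so the value rests on which libraries are kept.

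Heat shock members of the stress list were mostly called lower, 6 of 6 Hsp70 copies and 8 of 9 others, a subset chosen after the result and not tested as a list. Hsp70Aa and Hsp70Ab, with identical counts, are not separate measurements among the 6. Reads shared between Hsp70 copies cannot account for the fall of the 8 other members, which says nothing about the copies themselves. In 12 response genes not looked at before the median was −0.39, with 5 lower and 3 higher, which is in line with a heat shock response more active in control heads. Camera did not separate these genes from the others (p = 0.102, and p = 0.254 with an estimated correlation). A difference in handling or temperature between the groups cannot be told apart from the transgene, since 0 label fields differed between libraries of one group.

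Of the 1359 genes called lower, 53 were 5S rRNA entries out of 84 tested, and 84.5% of the tested entries shared their 4 counts with another. With 1 entry kept per set of entries with identical counts, the test called 1651 genes higher and 1334 lower.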
